A study of Mus musculus with 34 samples.

How the data were processed

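The deposited series held 34 Affymetrix arrays of 22690 probe sets from mice of mixed C57BL6/129SV strain, per the labels. Muscle glycogen synthase knockout mice and wild-type mice at 3 months gave tibialis (4 and 4 arrays), gastrocnemius (3 and 5) and liver (4 and 4). GSL30 mice and wild-type mice at 8 months gave gastrocnemius (5 and 5). The labels state RNA extraction with TRIzol and RNeasy, standard Affymetrix target preparation, and starting amounts of about 5 µg of RNA for muscle and 10 µg for liver. The software that summarised the probes is not given in the sources used here.

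The values were used as deposited by the authors, in units of intensity on a linear scale. Dropping the lowest and highest 2% of probe sets gave means of 1000.34 to 1000.49 in every array, so each array had been scaled to a trimmed mean of about 1000, as read from the values. Array medians ran from 296 to 440.3, and the largest ratio of medians within a comparison was 1.26. Correlations between arrays of a comparison ran from 0.897 to 0.980, and no pair of arrays shared more than 0.155% identical values. Values below 0 were set to 0, and log2(value + 50) was taken without further normalization, so every fold change and group difference is on the log2(value + 50) scale.

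Each comparison was fitted on its own arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes); version 1.17.8 of data.table handled the values. Control probe sets (64) were left out, as were probe sets under the 40th percentile of mean log2 value, which left 13576 in each comparison. Adjusted p is Benjamini-Hochberg over those probe sets, and a probe set passed under 0.05. P-values measure spread between these samples, because the labels do not say whether each array came from a separate animal. Gene symbols came from the supplied probe annotation, in which 20393 probe sets had 1 symbol, 691 had several and 1606 had none. Where groups did not overlap, the share of probe sets separated by chance was computed from the group sizes.

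Gene lists (48, of 806 entries, 702 with a probe set and 3 of these matched through an older symbol) were written before the data were examined. Each list with at least 5 measured genes was tested two-sided with camera in limma, with the brightest probe set per gene and a correlation between genes set to 0.01, and adjusted by Benjamini-Hochberg over the lists of a comparison. The same test with the correlation estimated from the data is given beside each call of the main fits and contrasts. The alternative fits described below used the set correlation unless stated. Camera ranks a list against all other genes, so its direction can differ from the sign of the list median. Genes of a list were also adjusted over the list alone. Differences between effects were fitted as contrasts over 16 arrays (gastrocnemius minus tibialis), 24 arrays (liver minus the mean of both muscles) and 18 arrays (GSL30 minus knockout in gastrocnemius). Overlaps of called probe sets were tested with Fisher exact tests adjusted over 20. Measures of 1 value per array were compared by exact two-sided permutation.

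Genes were named by a rule set before the data were examined. It took every Gys1 probe set, the 8 highest and 8 lowest called genes of non-overlapping groups, up to 2 called genes from each list by smallest p, and genes of glycogen metabolism. Where fewer than 10 genes passed, the 10 of smallest p were named as short of the threshold. Up to 10 genes of each overlap and 6 of each difference of effects were added. Genes outside the rule are said to be chosen after their values were seen.

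Alternatives set before the data were examined were quantile normalization, a common median, pseudocounts of 1 and 200, no filter for dim probe sets, a filter at the 60th percentile, all 34 arrays in 1 fit, a trended and robust eBayes, array weights, each array left out, 1 probe set per gene, the estimated correlation, and an adjusted p under 0.1 for overlaps. A sex covariate was planned only if the Xist minus Y-linked score spanned over 3 log2 units within a comparison. It spanned at most 1.50, so that covariate was not run. After the data were seen, 3 more were added for the gastrocnemius arrays. These were a hepatocyte score (mean of 12 genes) as covariate, 2863 probe sets over 2-fold brighter in wild-type liver than in wild-type tibialis left out, and arrays of high hepatocyte score left out. The last left out 4 arrays over 13 at 3 months (wild type 1, 2 and 4 and knockout 1) and 2 arrays over 9.5 at 8 months (wild type 2 and 5). A further 472 probe sets, bright in wild-type liver and at least 20-fold dimmer in wild-type tibialis, gave each gastrocnemius array a median percent of the liver level.

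The steps were tried on values simulated with 200 changed probe sets of 13576. With the group sizes of tibialis, 3-month gastrocnemius, liver and 8-month gastrocnemius they recovered 77, 61, 71 and 75% of 2-fold changes and 83, 82, 80 and 83% of 4-fold changes. False calls made up 4.76, 5.30, 3.21 and 3.07% of all calls and 0 had the wrong sign. With 2 of 40 lists shifted, both were called and 0 others were. Probe sets were simulated independently, without the correlation between genes or the shared array effects that real arrays can hold. These error rates therefore need not carry over to the real data, where regrouped 3-month gastrocnemius arrays gave up to 17 lists and 767 calls. Raw image files and the mapping of probes to a genome were not analysed here.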

Results

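Muscle glycogen synthase knockout mice, mice of the GSL30 line and their wild-type groups were compared in tibialis, gastrocnemius and liver. Fold changes are log2 differences on the log2(value + 50) scale with the standard error (SE) from limma, and group levels are mean intensity ± SD. Adjusted p is from limma with Benjamini-Hochberg adjustment over 13576 probe sets in each comparison.

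Gys1 was read by a brighter and a dimmer probe set, and the labels do not say whether these lie in the disrupted part of the gene or read the transgene. In tibialis the brighter read 9636, 9958, 9308 and 8184 in the wild-type arrays and 34.2, 34.6, 58.7 and 72.5 in the knockout arrays. In gastrocnemius at 3 months it read 4871, 4437, 6378, 3955 and 5525 in wild type and 165, 67.1 and 58.1 in knockout. The liver arrays read 48.2, 42.2, 72.2 and 64.4 in wild type and 18.6, 20.7, 60 and 51.9 in knockout, levels too dim to be tested and overlapping between groups. In gastrocnemius at 8 months the wild-type arrays read 6390.1, 5852, 5840, 7185 and 6158, and the GSL30 arrays read 10404, 9106, 8671, 7896 and 9500.5.

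Gys1 by the brighter probe set fell in knockout tibialis from 9271 ± 772 to 50 ± 18.9, a level as dim as in liver, so that at most 0.539% of the wild-type level was left (−6.56, SE 0.15, n = 4 and 4, adjusted p = 3.06e-08). In knockout gastrocnemius it fell from 5033 ± 948 to 96.7 ± 59.3, again near background, so that at most 1.92% was left (−5.17, SE 0.25, n = 3 and 5, adjusted p = 7.22e-05). In GSL30 gastrocnemius it rose from 6285 ± 553 to 9115 ± 935 (0.53, SE 0.11, n = 5 and 5, adjusted p = 0.0247). Left-out arrays kept the rise at 0.48 to 0.58 while its call ended in 5 of 10 such fits. The call also ended without the dim filter (0.53, adjusted p = 0.0564), without arrays of high hepatocyte score (0.49, adjusted p = 0.103) and with that score as covariate (0.52, adjusted p = 0.202). Liver read 37.8 ± 21.2 in knockout and 56.8 ± 13.9 in wild type. Gys1 by the dimmer probe set fell by 4.97 (SE 0.27, adjusted p = 3.97e-05) in knockout tibialis, to 23.4 ± 10.2 from 2405 ± 1063. It fell by 4.69 (SE 0.37, adjusted p = 0.00200) in knockout gastrocnemius, to 64.5 ± 83.2 from 2508 ± 465. In GSL30 it read 6619 ± 1488 against 2281 ± 1242 (1.84, SE 0.52, adjusted p = 0.0637) and did not pass, with wild-type replicate 5 at 289.4 and the other wild-type arrays at 2036 to 3332. In liver the dimmer probe set read 26.4 ± 6.23 in knockout and 29.1 ± 12.9 in wild type.

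**Figure D1:**
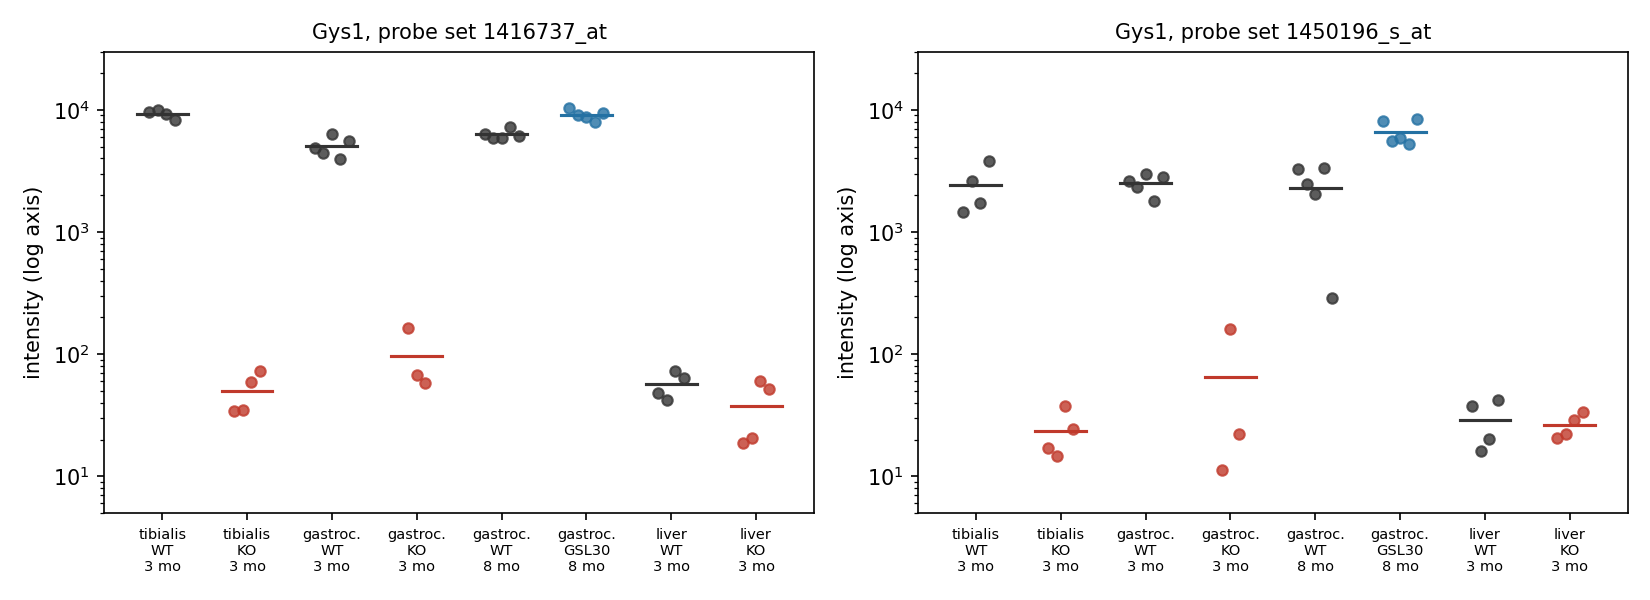
Gys1 intensity in every array for its probe sets on a log axis, with a line at the group mean. Black marks wild type (WT), red knockout (KO) and blue GSL30.

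Single genes of glycogen and glucose handling changed in knockout tibialis (n = 4 and 4), while neither list shifted as a whole. Gbe1, which encodes the glycogen branching enzyme, rose from 1399.7 ± 69.1 to 3163 ± 149.6 (1.15, SE 0.10, adjusted p = 6.99e-04), and Mlxipl, a glucose-responsive transcription factor, rose by 1.01 (adjusted p = 0.00286). Slc2a3, a glucose transporter, fell from 765 ± 76.1 to 249 ± 20.1 (−1.45, SE 0.11, adjusted p = 4.58e-04), and Pfkfb3, which makes an activator of glycolysis, fell from 5939 ± 987 to 2199 ± 386 (−1.41, SE 0.16, adjusted p = 0.00329). Ppp1r1a, an inhibitor of protein phosphatase, fell from 1806 ± 123 to 181 ± 70.6 (−3.05, SE 0.20, adjusted p = 1.82e-04). Pdhb, a pyruvate dehydrogenase subunit, rose by 0.61 (adjusted p = 0.0191). Hk2, a hexokinase gene chosen after its values were seen, rose by 0.56 (adjusted p = 0.0408).

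The largest rise in tibialis was that of Ifi30, a lysosomal thiol reductase, from 465 ± 80.1 to 4648 ± 770.3 (3.19, SE 0.16, adjusted p = 2.24e-05). Myl3, the slow and cardiac myosin light chain, rose from 2746 ± 1083 to 14814 ± 2550 (2.47, SE 0.25, adjusted p = 0.00176). Qprt of NAD synthesis rose by 2.14 (SE 0.25, adjusted p = 0.00343) and G0s2, an inhibitor of lipolysis, by 1.92 (SE 0.30, adjusted p = 0.0155). Aacs, which activates acetoacetate, rose from 292 ± 74.1 to 1129.6 ± 98.1 (1.81, SE 0.16, adjusted p = 0.00104). Wnt4 fell by 2.30 (SE 0.26, adjusted p = 0.00284), Agt by 2.09 (adjusted p = 0.00256), Dkk3 fell by 1.83 (adjusted p = 0.00284) and Adhfe1 by 1.69 (SE 0.13, adjusted p = 4.58e-04). Gpx3 and Gstm2 of glutathione metabolism fell by 0.95 and 0.84 (adjusted p = 0.00464 and 0.00611). The regeneration genes Actc1 and Chrna1 rose by 1.13 and 0.74 (adjusted p = 0.0440 and 0.0451), while the regeneration list did not shift (6 of 11 positive, adjusted p = 0.498 by camera).

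In all, 190 probe sets passed in tibialis, of which 90 rose and 100 fell (73 and 78 genes), and 68 of them moved over 2-fold. A gene was counted if any of its probe sets passed. Of 78 called genes with several tested probe sets, 65 were called by only some of them, and 0 were called in both directions. Leaving out 1 array gave 63 (without knockout replicate 2) to 300 calls (without wild-type replicate 4). At unadjusted p under 0.05 there were 2032, with 678.8 expected by chance. Groups did not overlap in 1368 of 13576 probe sets (10.1%), against a chance share of 2.86%. Of 28 named probe sets besides Gys1, 19 kept their call in every fit with 1 array left out that tested them. In the fits without a wild-type array only 27 of the 28 stayed above the dim filter. G0s2 lost its call without wild-type replicate 3 or knockout replicate 2.

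Of 38 gene lists 5 passed in tibialis by camera, and 0 with an estimated correlation (1 at unadjusted p under 0.05). Endothelial markers rose together (median 0.40, 11 of 11 positive, adjusted p = 0.00237 by camera, adjusted p = 0.658 with an estimated correlation). No member passed over all probe sets and 5 passed adjusted over the list alone, which were Esam, Kdr, Pecam1, Emcn and Tek. Interferon response genes rose (0.24, 13 of 16 positive, adjusted p = 0.0327 by camera, adjusted p = 0.824 with an estimated correlation), with 0 members passing in limma adjusted over the list alone. Ribosomal protein genes fell (−0.16, 20 of 21 negative, adjusted p = 0.00149 by camera, adjusted p = 0.824 with an estimated correlation), again with 0 members passing adjusted over the list alone. Lysosome and autophagy genes fell (−0.17, 17 of 22 negative, adjusted p = 0.00405 by camera, adjusted p = 0.824 with an estimated correlation), with Bnip3, Map1lc3b, Map1lc3a, Ctsl and Ulk1 passing adjusted over the list alone. Tendon and fibroblast markers fell (−0.34, 9 of 11 negative, adjusted p = 0.00464 by camera, adjusted p = 0.824 with an estimated correlation), and Fmod fell by 0.91 (adjusted p = 0.0293). Adjusted over the list alone, 3 of these markers fell and 1 rose.

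The glycogen metabolism list did not shift as a whole in tibialis (24 genes, median −0.10, adjusted p = 0.559 by camera). Adjusted over the list alone, 2 of its genes rose (Gbe1 and Stbd1) and 2 fell (Gys1 and Phkg1), where Stbd1 stood at 0.93 (adjusted p = 0.0531) and Phkg1 at −0.42 (adjusted p = 0.157) over all probe sets. Glucose uptake and glycolysis genes had a median of 0.02, a mean of −0.07 and a downward direction in camera (adjusted p = 0.893). Slow fibre genes stood at a median of 0.16 (8 of 13 positive, adjusted p = 0.0806), with Myl3 called and 4 genes passing adjusted over the list alone. Myh7, the slow myosin heavy chain, chosen here after its values were seen, read 762 ± 540 in knockout and 780 ± 255 in wild type (exact two-sided permutation p = 0.943). The antioxidant list (2 fell, 3 adjusted over the list alone, adjusted p = 0.0891) and oxidative phosphorylation (adjusted p = 0.788) did not pass.

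Knockout gastrocnemius (n = 3 and 5) shared many of its largest changes with tibialis. Odc1, which starts polyamine synthesis, fell from 12346 ± 1117 to 2965 ± 465 (−2.05, SE 0.15, adjusted p = 0.00112). Dkk3, a secreted relative of Wnt inhibitors, fell from 1002 ± 199.9 to 208 ± 20.5 (−2.01, SE 0.18, adjusted p = 0.00264), and 1700001O22Rik fell by 1.70 (SE 0.16, adjusted p = 0.00388). The Dkk3 value is from another probe set than the tibialis value above. It stood at −1.37 in tibialis (adjusted p = 0.0449), and the probe set given for tibialis stood at −1.64 in gastrocnemius (adjusted p = 0.0392). Mid1ip1, a regulator of fatty acid synthesis, rose from 2049 ± 423 to 5194.5 ± 50.1 (1.35, SE 0.19, adjusted p = 0.0392). Myl3 rose from 10034 ± 1227 to 21665 ± 3031 (1.11, SE 0.15, adjusted p = 0.0392). This Myl3 probe set also differs from the one given above for tibialis. In tibialis it read 8536 ± 2983 in wild type and 32995 ± 2671 in knockout.

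Aacs rose by 1.28 in gastrocnemius (adjusted p = 0.0454), Speg by 1.15 (adjusted p = 0.0453), Car14 by 0.89 (adjusted p = 0.0351) and Tecr by 0.86 (adjusted p = 0.0392). Fgfbp1 fell by 1.87 (adjusted p = 0.0350), Ppp1r1a by 1.68 (adjusted p = 0.0392), Ddit4l by 1.37 (adjusted p = 0.0392) and Gdap1 by 1.12 (adjusted p = 0.0454). Of the glycogen genes, Gbe1 stood at 0.89 (adjusted p = 0.133) and Stbd1 at 0.93 (adjusted p = 0.0758), and both passed adjusted over the list alone (0.00439 and 0.0018). The glycogen metabolism list as a whole had a median of 0.13 (adjusted p = 0.441 by camera). In total 20 probe sets passed, 6 higher and 14 lower (6 and 8 genes), 17 of them over 2-fold, with 1545 at unadjusted p under 0.05. Of 8 called genes with several tested probe sets, 5 were called by only some of them. Leaving out 1 array gave 7 to 10 calls for 7 of the 8 arrays and 25 without wild-type replicate 2. Groups did not overlap in 1355 of 13576 probe sets (9.98%), against a chance share of 3.57%. Of 13 named genes besides Gys1, only Odc1, Dkk3 and 1700001O22Rik kept their call whichever array was left out, as Gys1 did.

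Of 38 lists 16 passed in knockout gastrocnemius by camera, 6 higher and 10 lower, and 0 with an estimated correlation (3 at unadjusted p under 0.05). Slow fibre genes rose together (median 0.83, 12 of 13 positive, adjusted p = 5.26e-07 by camera, adjusted p = 0.365 with an estimated correlation). Myl3 alone passed over all probe sets and 10 genes passed adjusted over the list alone. The mean of the list per array was 13.09 ± 0.18 against 12.43 ± 0.27 (exact two-sided permutation p = 0.0179, the smallest possible with 3 and 5 arrays), while fast fibre genes differed by −0.07 (exact p = 1). Without wild-type replicate 2 fast fibre genes stood 0.21 higher in knockout (exact two-sided permutation p = 0.143) and slow fibre genes 0.68 higher (exact p = 0.0571). Endothelial markers rose (0.34, 10 of 11 positive, adjusted p = 1.77e-04, adjusted p = 0.365 with an estimated correlation), with 5 genes passing adjusted over the list alone. Genes of oxidative phosphorylation rose (0.14, 39 of 41 positive, adjusted p = 0.00554, adjusted p = 0.704 with an estimated correlation), as did those of the citric acid cycle (0.14, 20 of 22 positive, adjusted p = 0.0207, adjusted p = 0.630 with an estimated correlation). Smooth muscle genes (0.38, 6 of 6 positive, adjusted p = 0.00275, adjusted p = 0.365 with an estimated correlation) and Schwann cell genes (0.36, 5 of 5 positive, adjusted p = 0.0073, adjusted p = 0.365 with an estimated correlation) also rose, with 1 and 3 genes passing adjusted over the list alone. With the hepatocyte score as covariate, without liver-bright probe sets and without arrays of high score, adjusted p was 4.13e-04, 0.0815 and 0.173 for oxidative phosphorylation, 0.0151, 0.00996 and 0.138 for smooth muscle and 0.0151, 0.0277 and 0.00148 for Schwann cell genes.

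Transcripts bright in liver were present in the 3-month gastrocnemius arrays, at levels that varied widely within the wild-type group. Alb read 78705 ± 94063 in wild-type gastrocnemius (19232 to 245380, median 36873), 29019.9 ± 12275 in knockout gastrocnemius, 389 ± 86.2 in wild-type tibialis and 63649.8 ± 4437 in wild-type liver. Over 472 liver probe sets the median level was 16.2, 23.9, 4.24, 25.5 and 1.54% of wild-type liver in the wild-type arrays and 6.79, 2.35 and 1.44% in the knockout arrays. Hepatocyte genes fell (−1.37, 12 of 12 negative, adjusted p = 1.52e-04 by camera, adjusted p = 0.527 with an estimated correlation), while their mean per array, 12.27 ± 0.97 against 13.62 ± 1.57, did not separate the groups (exact two-sided permutation p = 0.232). Bile acid genes (−1.28, 15 of 15 negative, adjusted p = 5.26e-07, adjusted p = 0.512 with an estimated correlation) and acute phase genes (−1.39, 14 of 14, adjusted p = 1.70e-05, adjusted p = 0.527 with an estimated correlation) fell beside them. So did drug metabolism (−0.84, 15 of 18, adjusted p = 1.77e-04, adjusted p = 0.587 with an estimated correlation) and male-biased liver genes (−1.39, 7 of 7, adjusted p = 3.95e-04, adjusted p = 0.512 with an estimated correlation). With the hepatocyte score as covariate, bile acid (adjusted p = 0.0662), acute phase (0.321), drug metabolism (0.943) and male-biased liver genes (0.123) did not pass, and the hepatocyte list defines that score.

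**Figure D2:**
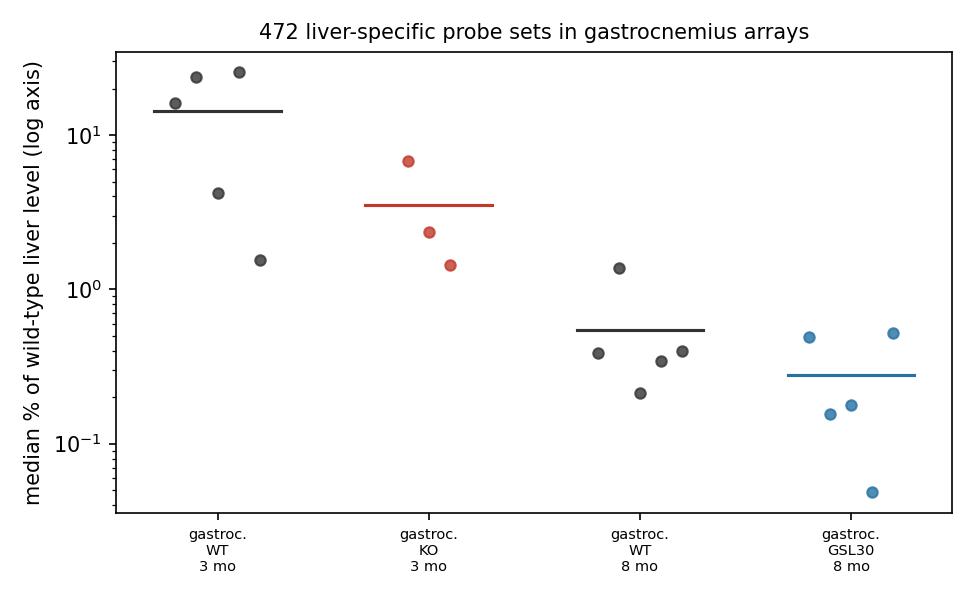
Median intensity of 472 liver probe sets in each gastrocnemius array as a percent of the wild-type liver level, on a log axis with a line at the group mean. The probe sets were bright in wild-type liver and at least 20-fold dimmer in wild-type tibialis.

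Several metabolic lists fell in knockout gastrocnemius alongside the liver transcripts. Fatty acid uptake and oxidation fell (−0.22, 19 of 26 negative, adjusted p = 6.42e-04 by camera, adjusted p = 0.512 with an estimated correlation), with 3 genes passing adjusted over the list alone. It no longer passed with the hepatocyte score as covariate (adjusted p = 0.194) or with liver-bright probe sets left out (adjusted p = 0.0815), and passed without arrays of high score (adjusted p = 0.00154). Antioxidant genes (−0.30, 14 of 18 negative, adjusted p = 1.93e-04, adjusted p = 0.365 with an estimated correlation) and unfolded protein response genes (−0.26, 15 of 20, adjusted p = 1.93e-04, adjusted p = 0.365 with an estimated correlation) fell. Cholesterol synthesis genes (−0.35, 8 of 11, adjusted p = 0.0107, adjusted p = 0.490 with an estimated correlation) and macrophage markers (−0.18, 10 of 15, adjusted p = 0.0073, adjusted p = 0.512 with an estimated correlation) fell as well. In the same order of added fits, adjusted p was 0.0151, 0.115 and 0.00148 for antioxidant genes, 0.0822, 0.292 and 0.0408 for the unfolded protein response, and 5.45e-04, 0.00539 and 0.0788 for macrophage markers. Cholesterol synthesis passed in none (0.0662, 0.992 and 0.742), and its median turned to 0.06 and 0.09 without liver-bright probe sets and without arrays of high score. At the set correlation the slow fibre rise passed by camera in every added fit, with adjusted p = 8.70e-09 under the covariate (0.364 with an estimated correlation), 6.06e-07 without liver-bright probe sets and 5.81e-04 without arrays of high score. Endothelial markers passed in each as well (adjusted p = 3.85e-04, 0.00118 and 0.00148), whereas the citric acid cycle passed only under the covariate (0.0326, 0.129 and 0.742).

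Knockout liver (n = 4 and 4) differed in 1 probe set. The transcript 0610005C13Rik fell from 4725 ± 11.4 to 969 ± 153 (−2.24, SE 0.13, adjusted p = 8.93e-05). The liver form Gys2 stood at −0.41 (adjusted p = 0.584), and the glycogen metabolism list had a median of 0.03 with 0 genes called by limma (adjusted p = 0.63 by camera). At unadjusted p under 0.05 there were 1131 probe sets, with 678.8 expected. Groups did not overlap in 702 of 13576 probe sets (5.17%), against a chance share of 2.86%.

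The liver genes nearest to the threshold did not pass, and they were Eif4e3 at −1.49 (adjusted p = 0.0735), Abcc6 at −1.28 (adjusted p = 0.0866), Lamb3 at −1.31 (adjusted p = 0.170) and Mgll at −1.01 (adjusted p = 0.182). Pctp stood at −0.73 (adjusted p = 0.182), Pspn at 0.72 (adjusted p = 0.214), and Acot8, Elovl5 and Uri1 at −0.76, −0.78 and −1.68 (adjusted p = 0.216 each).

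Of 36 lists 10 passed in knockout liver by camera, 3 higher and 7 lower, and 0 with an estimated correlation (2 at unadjusted p under 0.05). Fatty acid uptake and oxidation genes fell together (median −0.37, 23 of 25 negative, adjusted p = 1.61e-09 by camera, adjusted p = 0.647 with an estimated correlation). Limma called 0 of them over all probe sets, while 4 passed adjusted over the list alone, which were Ehhadh (−1.11), Eci1 (−0.48), Cpt2 (−0.50) and Cd36 (1553 ± 454 against 3119 ± 646). Fatty acid synthesis genes fell in camera (−0.03, 10 of 18 negative, adjusted p = 0.0458, adjusted p = 0.693 with an estimated correlation), with Elovl5, Fads2, Mogat1 and Acacb passing adjusted over the list alone. Proteasome genes (−0.11, 24 of 27 negative, adjusted p = 0.00122, adjusted p = 0.647 with an estimated correlation) and heat shock genes (−0.18, 11 of 13, adjusted p = 0.0143, adjusted p = 0.647 with an estimated correlation) fell. Interferon response genes fell (−0.22, 14 of 16 negative, adjusted p = 0.0040, adjusted p = 0.693 with an estimated correlation). Unfolded protein response genes rose (0.22, 17 of 19 positive, adjusted p = 0.00122, adjusted p = 0.647 with an estimated correlation), as did ribosomal protein genes (0.13, 18 of 21, adjusted p = 0.0190, adjusted p = 0.908 with an estimated correlation) and cell cycle genes (0.23, 5 of 5, adjusted p = 0.0458, adjusted p = 0.647 with an estimated correlation). Markers of other tissues moved in the same arrays, with pancreas genes at −1.77 (adjusted p = 0.00622, adjusted p = 0.693 with an estimated correlation) and adipocyte markers at −0.19 (adjusted p = 0.0458, adjusted p = 0.693 with an estimated correlation). The skeletal muscle actin Acta1 read 286 ± 368 in knockout liver (75.2 to 836.9) and 41.5 ± 20.2 in wild type (29.5 to 71.6; exact two-sided permutation p = 0.0286, the smallest possible).

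Genes of gluconeogenesis, fatty acid uptake and slow fibres fell in GSL30 gastrocnemius (n = 5 and 5). Fbp2, the muscle fructose bisphosphatase, fell from 5190.1 ± 816 to 2022 ± 218 (−1.33, SE 0.14, adjusted p = 0.00134), and Pygl, the liver form of glycogen phosphorylase, fell by 0.93 (adjusted p = 0.0168), a gene also brighter in liver than in tibialis. Cd36, a fatty acid transporter, fell from 16485 ± 1312 to 9272 ± 1092 (−0.83, SE 0.12, adjusted p = 0.00511), and Fabp4 fell from 2701 ± 474 to 933 ± 164 (−1.48, SE 0.16, adjusted p = 0.00134). Myh7, the slow myosin heavy chain, fell from 4159 ± 802 to 1746 ± 509 (−1.25, SE 0.19, adjusted p = 0.00636), and Tnnt1 fell by 1.28 (SE 0.22, adjusted p = 0.0102). The cardiac actin Actc1 rose from 5378 ± 1578 to 19029 ± 2141 (1.85, SE 0.17, adjusted p = 0.00134).

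The largest rise in GSL30 was that of Crip3, from 127 ± 68.2 to 857 ± 188 (2.42, SE 0.25, adjusted p = 0.00134). Dnase1 rose by 2.33 (adjusted p = 0.00398), Opn1mw by 2.05 (adjusted p = 0.0316), Cpne2 by 1.80 (adjusted p = 0.00636), Panx1 by 1.73 (adjusted p = 0.00447) and Cuzd1 by 1.44 (adjusted p = 0.00636). Desmin (Des) rose from 25559.9 ± 3324 to 43094 ± 7219 (0.75, adjusted p = 0.0163). Slc15a2 fell by 1.88 (adjusted p = 0.00567), Peg3 fell by 1.72 (adjusted p = 0.0116), Cbr2 by 1.56 (adjusted p = 0.00334) and Tpm3 by 1.35 (adjusted p = 0.0163). The smooth muscle genes Myh11 and Tagln fell by 1.04 and 0.93 (adjusted p = 0.00323 and 0.00568), while Des of the same list rose, and the smooth muscle list did not shift (3 of 6 negative, adjusted p = 0.306 by camera). The glucose and amino acid genes Got1 and Pgam1 fell by 0.74 and 0.64 (adjusted p = 0.0223 and 0.0228) and Idh2 of the citric acid cycle by 0.79 (adjusted p = 0.0307). Acot1 fell from 555 ± 206 to 239.8 ± 28.4 (adjusted p = 0.0212), Scd2 by 0.59 (adjusted p = 0.0163) and Dgat2 by 0.56 (adjusted p = 0.0354).

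In all, 585 probe sets passed in GSL30, 287 higher and 298 lower (249 and 244 genes), and 70 moved over 2-fold. Of 236 called genes with several tested probe sets, 212 were called by only some of them, and 0 were called in both directions. Leaving out 1 array gave 182 (without GSL30 replicate 2) to 772 calls (without GSL30 replicate 4). At unadjusted p under 0.05 there were 2908. Groups did not overlap in 1002 of 13576 probe sets (7.38%), against a chance share of 0.794%, and 502 of the 585 called probe sets were among them. Some transcripts of liver were lower in GSL30 than in its wild-type group, where Ttr fell by 2.72 (SE 0.47, adjusted p = 0.0112), Alb from 4798 ± 3037 to 1050.4 ± 639.6 (−2.11, SE 0.39, adjusted p = 0.0155) and Apoa2 by 1.91 (adjusted p = 0.0428). The hepatocyte score stood at 8.42 ± 0.38 against 9.62 ± 0.68 (exact two-sided permutation p = 0.00794), without overlap between groups, so a covariate for it stood for the group as well and ended all 47 named calls. Over 472 liver probe sets the groups overlapped, at 0.0485 to 0.522% of the liver level in GSL30 and 0.213 to 1.38% in wild type, and Fgb and Cps1 did not separate them (exact two-sided permutation p = 0.183 and 0.246). Leaving out arrays of high score kept 23 of 46 named calls. Besides Gys1, 27 of 47 held in every fit with 1 array left out that tested them. In several of those fits only 46 of the 47 stayed above the dim filter.

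Of 40 lists 14 passed in GSL30 by camera, 1 higher and 13 lower, and 3 with an estimated correlation. Slow fibre genes fell together (median −0.89, 12 of 13 negative, adjusted p = 5.39e-09 by camera, adjusted p = 0.0363 with an estimated correlation), and 7 genes passed over all probe sets (11 adjusted over the list alone). Their mean per array was 11.83 ± 0.17 against 12.62 ± 0.15 (exact two-sided permutation p = 0.00794, the smallest possible), while fast fibre genes differed by 0.13 (exact p = 0.349). Myh2, the called gene of the fast fibre list, fell from 23916 ± 3171 to 15284 ± 2381 (−0.65, adjusted p = 0.0282). Endothelial markers fell (−0.52, 11 of 11 negative, adjusted p = 2.56e-08, adjusted p = 0.0363 with an estimated correlation), with 5 genes passing and 9 adjusted over the list alone. Cdh5 fell from 3120.0 ± 346 to 1834 ± 173 (−0.75, SE 0.12, adjusted p = 0.00706) and Esam by 0.64 (adjusted p = 0.0120), and the other called genes, Pecam1, Cldn5 and Ramp2, chosen after their values were seen, fell by 0.81, 0.81 and 0.44. Gluconeogenesis genes fell (−0.43, 11 of 12 negative, adjusted p = 4.72e-05, adjusted p = 0.0363 with an estimated correlation), with 2 genes passing and 6 adjusted over the list alone. With the hepatocyte score as covariate these lists passed by camera at the set correlation (adjusted p = 9.73e-08 for slow fibre, 1.87e-05 for endothelial and 3.98e-04 for gluconeogenesis genes). That score separated the groups without overlap and so stood for the group as well. List results under it, here and for the lipid, matrix and proteasome genes below, therefore cannot decide for or against a part of liver RNA. The glycogen metabolism list did not shift (24 genes, adjusted p = 0.475), with Gys1 higher and Pygl lower.

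**Figure D3:**
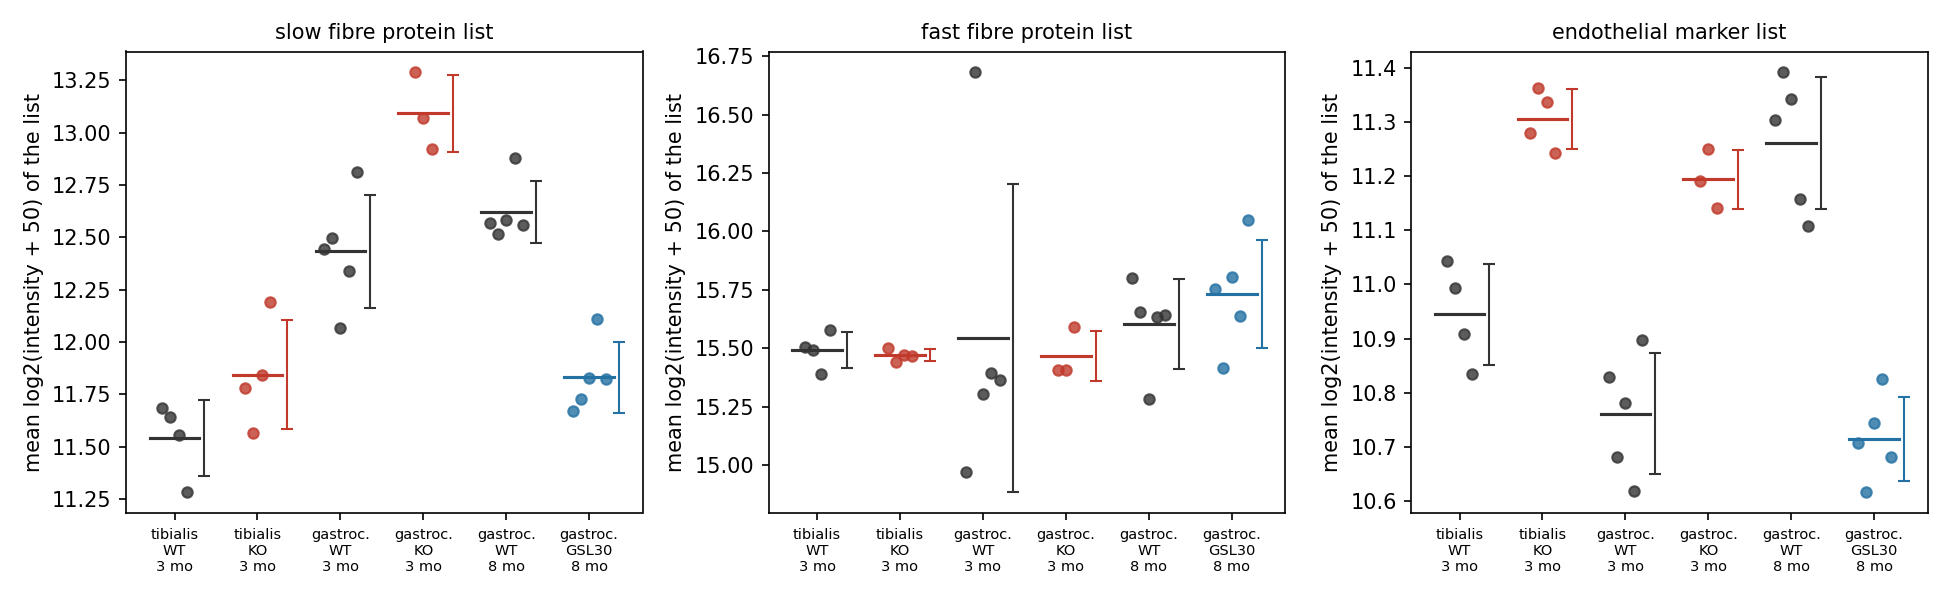
Mean log2(intensity + 50) of slow fibre, fast fibre and endothelial genes in every muscle array, with a line at the group mean and a bar of ± SD. Black marks wild type (WT), red knockout (KO) and blue GSL30.

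Lipid genes fell in GSL30 as groups. Fatty acid uptake and oxidation fell (−0.25, 22 of 25 negative, adjusted p = 4.72e-05 by camera, adjusted p = 0.261 with an estimated correlation), with 2 genes passing and 6 adjusted over the list alone. Fatty acid synthesis fell (−0.33, 14 of 16, adjusted p = 5.40e-04, adjusted p = 0.261 with an estimated correlation; 3 adjusted over the list alone), as did adipocyte markers (−0.64, 8 of 8, adjusted p = 8.53e-05, adjusted p = 0.344 with an estimated correlation; 6 adjusted over the list alone). With the hepatocyte score as covariate, fatty acid oxidation passed (adjusted p = 1.57e-05 by camera) as did adipocyte markers, and fatty acid synthesis did not (0.0595).

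Matrix genes fell as well, with Col4a1 and Fn1 lower by 0.58 and 0.57 (adjusted p = 0.0168 each), Thbs4 by 0.77 (adjusted p = 0.00772) and Comp by 0.52 (adjusted p = 0.0351). The extracellular matrix list fell (−0.21, 23 of 25 negative, adjusted p = 5.64e-05 by camera, adjusted p = 0.381 with an estimated correlation), with 4 genes passing and 7 adjusted over the list alone, as did tendon and fibroblast markers (−0.42, 11 of 11, adjusted p = 2.02e-04, adjusted p = 0.293 with an estimated correlation), with 4 passing on either adjustment. Under the covariate neither passed (adjusted p = 0.156 and 0.0595). Hepatocyte genes (−1.47, 8 of 8, adjusted p = 5.64e-05, adjusted p = 0.293 with an estimated correlation) and acute phase genes (−0.39, 6 of 6, adjusted p = 0.00761, adjusted p = 0.344 with an estimated correlation) fell beside them. Drug metabolism genes fell too (−0.46, 12 of 13, adjusted p = 1.04e-04, adjusted p = 0.189 with an estimated correlation). Acute phase and drug metabolism genes did not pass under the covariate (adjusted p = 0.931 and 0.0918).

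Proteasome genes rose in GSL30 (0.15, 25 of 28 positive, adjusted p = 5.20e-04 by camera, adjusted p = 0.416 with an estimated correlation), where Psmd4 rose by 0.50 (adjusted p = 0.0314) and 8 genes passed adjusted over the list alone. Interferon response genes (−0.23, 13 of 16 negative, adjusted p = 0.0189, adjusted p = 0.344 with an estimated correlation) and immediate early genes (−0.27, 14 of 19, adjusted p = 0.0484, adjusted p = 0.449 with an estimated correlation) fell. None of these passed under the covariate (proteasome genes included, with adjusted p = 0.239 for interferon and 0.0918 for immediate early genes).

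The knockout changes of tibialis and gastrocnemius overlapped. Of 12749 probe sets tested in both, 4 rose in both against 0.0395 expected (adjusted Fisher exact p = 2.60e-07) and 11 fell in both against 0.0999 expected (adjusted p = 4.78e-21). The genes were Gys1, Ppp1r1a, Dkk3, 1700001O22Rik, Aacs, Odc1, Gdap1, Myl3, Ddit4l, Mid1ip1 and Tecr. Among the falls, Gys1, Dkk3 and Odc1 were each counted by more than 1 probe set, and the fall of Gys1 was fixed by the knockout. The Fisher test treats probe sets as independent, so its p for the falls overstates the overlap. Of 182 tibialis calls measured in gastrocnemius, 162 had the same sign (89.0%), while the correlation over all probe sets was 0.207. Both called probe sets of the difference between the muscles belonged to Slc38a10, whose effect differed by −1.32 (adjusted p = 0.0340), with 1.61 in tibialis and 0.29 in gastrocnemius. That contrast had 0 calls in limma in 10 of 16 fits with an array left out (1033 to 1542 at unadjusted p under 0.05), and chance was not excluded for its 2 calls. With 0 limma calls in liver among probe sets tested also in tibialis, and 1 among those tested in gastrocnemius, the Fisher tests of overlap with liver could show nothing.

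The effects on liver and muscle differed in 93 probe sets (41 higher, 52 lower). The effect on Ifi30 differed by −2.43 between liver and the mean of both muscles (adjusted p = 1.11e-04), with 3.19 in tibialis, 1.71 in gastrocnemius and 0.02 in liver. Pfkfb3 differed by 1.70 (adjusted p = 9.10e-04), standing at 0.68 in liver, and Ppp1r1a by 2.07 (adjusted p = 9.10e-04). Ano10 differed by −1.53 and Slc38a10 by −1.16 (adjusted p = 3.98e-04 each), and Gys1 by 5.56 (adjusted p = 3.03e-12).

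Several genes called in both moved in opposite directions in knockout tibialis and GSL30 gastrocnemius. Between tibialis and GSL30, 9 probe sets rose and then fell against 1.76 expected (adjusted Fisher exact p = 4.29e-04) and 8 fell and then rose against 2.09 expected (adjusted p = 0.00578), while the correlation over all probe sets was −0.06. Myl3 made up 3 of the 9 and Gys1 itself 1 of the 8. Fabp4 stood at 1.17 in knockout tibialis and −1.48 in GSL30, Myl3 at 2.47 and −0.72, G0s2 at 1.92 and −0.88, and Ugp2 of glycogen synthesis at 0.77 and −0.67. Ppp1r1a (−3.05 and 0.74), Ddit4l (−1.27 and 0.76) and Tnfrsf19 (−1.30 and 1.08) went the other way. In the same direction 6 rose in both (adjusted p = 0.0217) and 6 fell in both (adjusted p = 0.0503), with Dkk3 at −1.83 and −1.19, Actc1 at 1.13 and 1.85, Mid1ip1 at 0.94 and 0.89, Otub2 at 1.19 and 1.35 and Tmem100 at −1.43 and −1.08. Between knockout and GSL30 gastrocnemius 4 probe sets moved the same way and 4 moved opposite ways, with 1 higher in both (adjusted p = 0.240), 3 lower in both (adjusted p = 0.0144), 2 higher then lower (adjusted p = 0.0217) and 2 lower then higher (adjusted p = 0.0755). Those lower in both belonged only to Dkk3, counted by more than 1 probe set, and Fgfbp1. Gys1 itself was among those lower then higher.

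Within gastrocnemius, the GSL30 effect differed from the knockout effect in 312 probe sets (88 higher, 224 lower), with 152 to 448 when 1 array was left out and 55 without arrays of high hepatocyte score. Gys1 differed by 5.70 (adjusted p = 2.28e-10), Odc1 by 1.65 (adjusted p = 3.71e-05) and Ppp1r1a by 2.42 (adjusted p = 1.82e-04), while Fbp2 differed by −2.01 (adjusted p = 2.38e-04), Myh11 by −1.97 (adjusted p = 1.94e-05) and Myl3 by −1.84 (adjusted p = 1.82e-04). The Odc1 and Myl3 values came from other probe sets than those given above for knockout gastrocnemius. That of Odc1 stood at −1.45 in knockout and 0.20 in GSL30, and that of Myl3 at −0.84 in GSL30. Slow fibre genes differed by a median of −1.43 (adjusted p = 5.90e-12 by camera, adjusted p = 0.0211 with an estimated correlation). Endothelial genes differed by −0.91 (adjusted p = 8.04e-11, adjusted p = 0.0107 with an estimated correlation). Age was 3 months in the knockout groups and 8 months in the GSL30 groups.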

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

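Every test weighed here, including the regrouping of arrays, was chosen only after the results were seen.

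Transcripts bright in liver were present in the 3-month gastrocnemius arrays. Distorted scaling of dim probe sets was excluded, because only 0.00420 of 6668 probe sets dim in liver and tibialis lay over 3-fold above tibialis. That test averaged over the arrays and could not show stretched bright values in a single array. Wild-type replicate 2 read 309794 for the Cre spike (others of its group 27754 to 40155) and 245380 for Alb, against 63649.8 ± 4437 in wild-type liver. Distorted bright values were therefore not excluded in that array. Mixed-in liver RNA was to lift at least 0.9 of 472 liver probe sets over 3-fold above tibialis, and under 0.5 was to exclude it. The share was 0.820, between these bounds. At the mean of 10.2% of the liver level in these arrays, mixing alone would lift only 399 of the 472 over 3-fold. The bound of 0.9 was thus out of reach, and that test could not decide whether liver RNA was in the samples. A narrower version over 399 probe sets, chosen by the level in the same arrays after the first fell short, gave 0.922 and was set aside because that choice fixed much of its outcome.

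Slow fibre genes were higher in knockout gastrocnemius and lower in GSL30 gastrocnemius. Dilution of muscle transcripts by liver RNA was excluded as the whole cause in knockout gastrocnemius, because the mean of slow fibre genes per array stayed 0.65 higher with the hepatocyte score as covariate (SE 0.22, p = 0.0318 in a linear model of 8 arrays, and adjusted p = 8.70e-09 by camera, adjusted p = 0.364 with an estimated correlation). Dilution as part of the rise stays open, because slow minus fast fibre genes did not decide there (exact two-sided permutation p = 0.143) and without wild-type replicate 2 fast fibre genes also stood 0.21 higher. In GSL30 dilution was excluded as the whole cause, because slow minus fast fibre genes differed (exact two-sided permutation p = 0.00794). Slow fibre genes differed by −0.79 there, while fast fibre genes did not separate the groups (0.13, exact p = 0.349), although Myh2 of that list fell. The hepatocyte score was also lower in GSL30 (8.42 ± 0.38 against 9.62 ± 0.68), so dilution would lower muscle transcripts in wild type rather than in GSL30. Uneven sampling of the muscle was not tested and stays open.

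The transcript 0610005C13Rik was lower in knockout liver and lies 9 annotated genes from Gys1 in the assembly GRCm38.p6. Of the other genes of smallest p in liver, Abcc6 and Uri1 also lie on chromosome 7, at 44 and 299 annotated genes from Gys1. The rest lie on other chromosomes. A genome segment linked to the targeted allele would place other changed genes nearby. Among 70 measured protein-coding genes within 100 on each side of Gys1, 1 (Abcc6) had an unadjusted p under 0.001 in liver against 26 of 8118 elsewhere (Fisher exact two-sided p = 0.207), so linkage and its absence cannot be told apart. With 0.320% of genes passing elsewhere, few were expected nearby, so the test had little power. Over all annotated genes the p was 0.0174 with 0610005C13Rik counted (2 of 60 against 26 of 8204) and 0.176 without it, so that value rests on the gene that prompted the test. In tibialis 5 of 66 protein-coding genes nearby had an unadjusted p under 0.001 against 141 of 8119 elsewhere (Fisher exact p = 0.00629, adjusted p = 0.0504 over 8 tests).

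Arrays were regrouped with the same group sizes, in all ways up to 56 and otherwise in 100 or 60 groupings, the real grouping included and the others drawn at random. Chance was taken as excluded where fewer than 1 in 20 groupings gave as many calls. For calls in tibialis chance was excluded, as 1 of 35 groupings gave as many as the real 190 and the highest other gave 0. It was also excluded by that bound in knockout gastrocnemius (2 of 56, 20 calls), although 1 other grouping gave 767, which points to a structure of the samples. That grouping differed by 2.48 in hepatocyte score, against −1.35 for the real one, and whether the score gave the 767 calls was not tested. In GSL30 chance was excluded, with 1 of 100 as large, 585 calls and 11 in the highest other. In liver chance was not excluded, with 5 of 35 as large, 1 call and 1 in the highest other. For differences between effects, chance was excluded for liver against both muscles (1 of 60, 93 calls, highest other 42) and, by the same bound, for GSL30 against knockout (2 of 60, 312 calls), although 1 other grouping gave more (376). For gastrocnemius against tibialis it was not excluded (4 of 60, 2 calls, highest other 409). What set apart the groupings of 376 and 409 calls was not tested.

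For numbers of gene lists, chance was not excluded in any comparison. In tibialis 13 of 35 groupings gave as many as the real 5 lists, with 10 in the highest other. In knockout gastrocnemius 9 of 56 gave as many as 16, with 17 in the highest other. In liver 4 of 35 gave as many as 10, with 11 in the highest other. In GSL30 15 of 100 gave as many as 14, with 16 in the highest other.

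Arrays far from their group were sought by a Dixon ratio, and chance alone marks about 1 in 20 groups. It marked 6 of 35 groups of array measures and 9 of 193 groups of named genes, where 9.65 were expected. Knockout gastrocnemius, with 3 arrays, was too small a group for this ratio and was not screened. Its replicate 1 had a Gapdh 3′ minus 5′ value of 0.34, against −0.16 in replicate 2 and −0.29 in replicate 3. Gastrocnemius wild-type replicate 2 at 3 months had a maximum of 310986 (others 49447 to 73305), a Cre spike of 309794 (others 27754 to 40155) and an actin 3′ minus 5′ value of −1.19 (others −0.44 to −0.26). Maxima of 79723 in tibialis knockout replicate 1 (others 71392 to 72186) and 106068 in liver knockout replicate 3 (others 78195 to 80247) were also marked. The Gapdh 3′ minus 5′ value was 0.10 in gastrocnemius wild-type replicate 5 at 8 months (others −0.24 to −0.18).

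In tibialis wild-type replicate 4, Dcxr read 364.1 (others 597 to 623) and Slc2a3 read 651.3 (others 799 to 806). Pdhb read 20688 in tibialis knockout replicate 2 (others 22917 to 23347), and Cyp27a1 read 2726 in knockout replicate 1 (others 2181 to 2241). Uri1 read 887.7 in liver wild-type replicate 1 (others 1498 to 1625). Gastrocnemius wild-type replicate 5 at 8 months read 289.4 for Gys1 by its dimmer probe set (others 2036 to 3332), 245.2 for Cacng6 (others 1061 to 1857) and 505.4 for Hsd17b7 (others 819 to 886). Cpne2 read 2826 in GSL30 replicate 2 (others 944 to 1147).

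Effects that differed between tissues or lines were these. Slc38a10 differed by −1.32 between gastrocnemius and tibialis. Between liver and both muscles Gys1 differed by 5.56, Ifi30 by −2.43, Ano10 by −1.53, Slc38a10 by −1.16, Pfkfb3 by 1.70 and Ppp1r1a by 2.07. Between GSL30 and knockout Gys1 differed by 5.70, Myh11 by −1.97, Odc1 by 1.65, Myl3 by −1.84, Ppp1r1a by 2.42 and Fbp2 by −2.01. The Odc1 and Myl3 values are again from other probe sets than those given for knockout gastrocnemius alone.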

How the results depend on the processing

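The fits with a hepatocyte covariate, without liver-bright probe sets and without arrays of high hepatocyte score were tests chosen only after the results were seen, and the other settings were set before. No paired analysis was possible because the labels give no animal identity and replicate numbers follow accession order only. No named gene, Gys1 value or overlap turned direction under these settings, and the cause was not tested except where named. In knockout gastrocnemius the median of cholesterol synthesis genes turned from −0.35 to 0.06 without liver-bright probe sets and to 0.09 without arrays of high score, and that of hepatocyte genes to 0.08 with their score as covariate, which its construction fixes. The fast fibre difference there turned from −0.07 to 0.21 without wild type 2, a value computed after the result was seen. Scaling by quantiles or a common median moved the share of higher calls by under 10 points in the main comparisons. For gastrocnemius minus tibialis both gave 3 calls with 1 higher (33.3%), against 0 of 2.

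With an estimated correlation the called lists numbered 0 in tibialis, 0 in gastrocnemius, 0 in liver and 3 in GSL30. Quantile normalization gave 9 lists in tibialis. Without the dim filter, calls numbered 96 in tibialis (9 lists), 7 in gastrocnemius, 259 in GSL30 with Gys1 at 0.53 (adjusted p = 0.0564), 193 for GSL30 minus knockout and 0 in limma for gastrocnemius minus tibialis (1794 at unadjusted p under 0.05). Overlaps then numbered 4 in the same direction for tibialis and gastrocnemius, 0 and 0 for gastrocnemius and GSL30 in the same and opposite directions by Fisher test, and 2 and 6 for tibialis and GSL30. A filter at the 60th percentile gave 288 calls in tibialis, 5 for gastrocnemius minus tibialis, and the dimmer Gys1 probe set at 1.84 in GSL30 (adjusted p = 0.0411).

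All 34 arrays in 1 fit gave 291 calls in tibialis, 306 in gastrocnemius, 32 in liver, 1093 in GSL30 with the dimmer Gys1 probe set at 1.84 (adjusted p = 0.00402), 6 for gastrocnemius minus tibialis and 670.0 for GSL30 minus knockout. The trended robust fit gave 321 in tibialis, 3 in liver and 6 for gastrocnemius minus tibialis. Array weights gave 335 in tibialis, 139 in gastrocnemius and 3 in liver. A pseudocount of 200 gave 3 in liver, 6 for gastrocnemius minus tibialis, and 1.71 for the dimmer Gys1 probe set in GSL30 (adjusted p = 0.0378), and a pseudocount of 1 gave 1 for gastrocnemius minus tibialis. At adjusted p under 0.1 the overlaps were 27 (from 15) for tibialis and gastrocnemius in the same direction, 9 and 10 (from 4 and 4) for gastrocnemius and GSL30 in the same and opposite directions, and 32 and 59 (from 12 and 17) for tibialis and GSL30.

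The hepatocyte covariate gave 10 lists in gastrocnemius (8 shared), 0 calls in limma in GSL30 (2349 at unadjusted p under 0.05), 7 lists there (5 shared), Gys1 at 0.52 (adjusted p = 0.202) and 642 calls for GSL30 minus knockout (312 shared). Leaving out liver-bright probe sets gave 6 lists in gastrocnemius (5 shared). Leaving out arrays of high score gave 4 calls in gastrocnemius (3 shared), 10 lists (7 shared) and the dimmer Gys1 probe set at −4.58 (adjusted p = 0.0784). In GSL30 it gave 153 calls (137 shared), Gys1 at 0.49 (adjusted p = 0.103) and the dimmer probe set at 1.19 (adjusted p = 0.0353), with 1 call for gastrocnemius minus tibialis and 55 for GSL30 minus knockout (46 shared).

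With each array left out, calls ran from 63 (without knockout 2) to 300 (without wild type 4) in tibialis and lists from 3 (knockout 4) to 8 (knockout 2). Every other tibialis array left 81 to 114 calls. In gastrocnemius calls ran from 7 (without wild type 5 or knockout 3) to 25 (wild type 2) and lists from 14 to 20, and 7 of 8 arrays left 7 to 10 calls. In liver calls ran from 1 to 8 (without knockout 2), with 2 without wild type 3, and lists from 6 (wild type 2 or knockout 3) to 12. In GSL30 calls ran from 182 (without GSL30 2) to 772 (without GSL30 4) and lists from 13 to 16. Gys1 there ran from 0.48 to 0.58 and lost its call without wild type 1 (adjusted p = 0.0542), wild type 3 (0.0620), GSL30 1 (0.0591), GSL30 2 (0.0636) or GSL30 5 (0.0601). The dimmer probe set ran from 1.24 to 2.07 and passed without wild type 5 at 1.24 (adjusted p = 0.0124). Gastrocnemius minus tibialis ran from 0 to 7 calls (7 without tibialis wild type 4), and the 10 fits of 0 calls in limma had 1033 to 1542 at unadjusted p under 0.05. Liver minus both muscles ran from 66 to 111 and GSL30 minus knockout from 152 (without knockout 1) to 448 (without wild type 5 at 3 months), with 167 and 189 without knockout 2 and 3. Gys1 ran from −6.66 to −6.48 in tibialis and −5.48 to −4.98 in gastrocnemius, and its dimmer probe set from −5.17 to −4.72 and −5.25 to −4.36.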

Other observations

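The tests of endothelial genes and the single-gene values of this part were chosen only after the results were seen. The camera tests of the pancreas, adipocyte and neutrophil lists were set before the data were examined, and were picked out here afterwards.

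Endothelial genes were higher in knockout muscle and lower in GSL30 gastrocnemius. In tibialis their mean per array was 11.31 ± 0.05 in knockout and 10.94 ± 0.09 in wild type (exact two-sided permutation p = 0.0286, the smallest possible). In gastrocnemius it was 11.19 ± 0.05 against 10.76 ± 0.11 at 3 months (exact p = 0.0179) and 10.72 ± 0.08 in GSL30 against 11.26 ± 0.12 (exact p = 0.00794). The difference between the GSL30 and knockout effects had a camera p = 2.67e-04 with an estimated correlation, adjusted p = 0.0107 over the lists. A change of endothelial transcripts in opposite directions with loss and gain of glycogen synthase remains a hypothesis, because it was found and tested on the same data and uneven sampling of the muscle was not tested.

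Pancreas genes were higher in wild-type liver than in knockout liver (median −1.77, 6 of 6 negative, adjusted p = 0.00622 by camera, adjusted p = 0.693 with an estimated correlation). Wild-type replicate 1 carried most of this, with Cpa1 at 17582, Prss2 at 16642, Cela1 at 18123 and Ctrb1 at 13909. Wild-type replicate 2 read 2153 for Cpa1, and the other liver arrays read 8.2 to 636. Adipocyte markers were lower in knockout liver (−0.19, 4 of 6 negative, adjusted p = 0.0458, adjusted p = 0.693 with an estimated correlation), where Cidec stood at −2.06 (adjusted p = 0.216). Neutrophil markers stood at −1.02 in knockout tibialis (6 of 6 negative, adjusted p = 0.0762 by camera) and did not pass.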
